A study of Caenorhabditis elegans with 16 samples.

How the data were processed

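RNA of whole young adults of the him-5(e1490) strain, sorted by sex and collected after 6 h on OP50 or PA14, was measured in 16 samples, 4 biological replicates of each sex on each bacterium. Per the labels, the libraries were made by a bulk form of MARS-seq, which reads the 3′ ends of transcripts and pools barcoded samples before linear amplification. The labels name cutadapt, STAR 2.4.2a, HTSeq and DESeq2 and the genome build WBcel235. Whether molecular identifiers were collapsed, and the strand setting of the counting, are not given in the sources used here.

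The values came from 1 table of 12181 genes deposited by the authors. Its first kind of value is raw counts per gene and sample, which the authors obtained with HTSeq and did not normalize. The table lists genes whose highest raw count over the 16 samples is at least 6. The second kind is a signal, the authors' normalized counts, and multiplying each by its sample's size factor gave back the raw count for 100% of the values (relative tolerance 1e-06). The authors' mean of the normalized counts over all samples is a signal of the same scale. The authors' log2 fold changes and adjusted p values (p_value) for 4 pairs of groups come from DESeq2. The other columns by the authors mark genes as passing, and a rule of adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean of at least 5 gave the same genes without exception. By that mark the authors' table passed 94 higher and 67 lower genes on PA14 in hermaphrodites, 56 and 38 in males, and 1484 and 433 between the sexes on OP50 and 1358 and 311 on PA14, and these included all 85 and 30 genes called here on PA14, 1535 of 1679 between the sexes on OP50 and 1318 of 1459 on PA14.

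Raw counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions. Each adjusted p of a gene in the text comes from this test unless another tool is named. Library sizes were scaled by TMM, with factors from 0.72 to 1.38. The filter filterByExpr kept 8648 genes and removed 3533. The model had 4 group means without an intercept and 12 residual degrees of freedom, and the biological coefficient of variation was 0.58. The contrasts were PA14 against OP50 in each sex, the difference of these responses, and male against hermaphrodite on each bacterium. P values were adjusted by the method of Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were computed as the absolute change divided by the square root of F. These choices, the gene lists, the rule for naming genes and the first set of alternatives below were made before the data were examined.

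Gene names were matched to Ensembl release 115, 10551 by gene name and 1352 by sequence name, while 278 were not matched and have no coordinates here. The 53 gene lists were fixed from general knowledge of the worm and covered immunity, stress, metabolism, tissue markers, signalling, germline and sex. Of these, 50 had at least 3 tested members. Lists could share genes, so that their tests are not independent. The infection response list also held genes of the lectin, lysozyme and dod lists, such as clec-4, clec-85, lys-2 and dod-24. Both the propionate shunt and the beta oxidation list held acdh-1 and ech-6. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The intracellular pathogen response genes, the receptor guanylyl cyclases and the male somatic genes had under 3 tested members and are not analysed here as lists.

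Named genes were, per comparison, up to 10 in each direction with the largest fold change among those with an adjusted p under 0.05, a mean raw count of at least 10 over the 8 libraries compared and no overlap in CPM between the groups, at most 2 of one name stem. Per list, up to 4 members with the smallest adjusted p under 0.05 were added, or 1 member as a value where none passed. The tested npr genes, daf-7, vit-2, vit-6, lov-1, pkd-2 and mab-3 were always looked at, and tph-1 is not analysed here. Of the genes of this rule that passed, fbxa-24 on PA14 in hermaphrodites and, between the sexes, lys-8, Y77E11A.14, gst-10, ckb-2, rpn-6.2, acdh-5, wrt-2 and cwp-5 on OP50 and ugt-13, dmsr-2, dpy-7 and rol-6 on PA14 had groups that overlapped, with 3 of 4 libraries beyond the other group. For all the others all 4 libraries lay beyond. Outside the rule, and after their values were seen, acdh-1 and zip-2 in hermaphrodites, sams-1 in males, npr-5, EEED8.3 and the genes drawn in the plot of 8 genes were chosen. Genes that overlap others or belong to near identical families are marked in the text as uncertain.

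CPM of single genes used the TMM-scaled library sizes, while summed CPM of gene groups and the CPM of npr-5 and lov-1 used plain total counts. Errors of CPM are SDs over 4 replicates. A ratio with 1 to 3 counts in the lower group has a 95% counting interval, and a group without counts was set to a floor of 3 counts over the group. Such intervals and floors cover counting error only. Summed CPM were compared between groups of 4 with two-sided exact permutation tests, whose smallest possible p is 0.0286, adjusted over 8 measures per comparison, and these tests were chosen after the values were seen. Principal components used log2 CPM with a prior count of 2. Correlations between replicates of a group were between 0.81 and 0.973, and the smallest chi-square per degree of freedom between replicates was 24.9, so that no library was a copy of another.

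The labels do not say whether a replicate number marks a shared day. In hermaphrodites, deviations from the group mean correlated between the OP50 and PA14 samples of a number at 0.67 to 0.81. Each OP50 sample correlated best with the PA14 sample of its own number. PA14 replicate 4, however, correlated better with OP50 replicate 3 (0.75) than with its own number (0.67). Between the sexes on PA14 they correlated at 0.17 to 0.67, while hermaphrodites replicates 2 and 4 correlated better with males of another number (0.55 and 0.57). For these comparisons the fit with the number as a block is given beside the unblocked one. Fitted to all 16 samples it kept 85 of 85 calls in hermaphrodites and 1455 of 1459 between the sexes on PA14, and fitted to only the 8 samples compared it kept 82 and 1035.

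The alternatives chosen beforehand were the size factors of DESeq2, library size alone, scaling without germline and cuticle genes, no filter and a filter of at least 10 counts in 8 samples, DESeq2 1.42.0, limma-voom, dispersions that are not robust, a block for replicates, each sample left out in turn, a fold minimum of 1 on the log2 scale and only the 8 samples compared. Chosen after seeing the data were a covariate for replicates 1 and 2 against 3 and 4, each of these pairs of replicates alone, the fit without OP50 males replicate 1 and PA14 males replicate 2, and the block with only the 8 samples compared. Called results were also set against all 35 splits of the 8 libraries of a comparison, or 100 draws of labels for the difference of the responses and the shared genes. Chosen after seeing the data were the 18 of these splits that balance replicates 1 and 2 against 3 and 4, and another 100 draws that swapped the bacteria only within a replicate number in hermaphrodites and within these pairs of replicates in males. On simulated data with these dispersions the test recovered 18 of 100 genes changed 4-fold on PA14 in hermaphrodites, 27 in males, 27 between the sexes on OP50 and 23 on PA14, and 1, 4, 1 and 3 of 100 changed 2-fold, with at most 1 gene called falsely.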

Results

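Transcripts of whole Caenorhabditis elegans young adults were counted after 6 h on Escherichia coli OP50, the standard laboratory food of the worm, or on Pseudomonas aeruginosa PA14, a bacterium that infects it. The animals carried him-5(e1490), a mutation that raises the share of males, had been grown at 22 °C, and were separated by sex. There were 4 biological replicates in each of 4 groups, 16 libraries in all. Total counts ranged from 3011817 in OP50 males replicate 1 to 9372206 in OP50 hermaphrodites replicate 1, and 3 counts stood between 0.32 and 0.996 CPM, the scale used for levels. The mean total was 7043650 ± 1625000 (SD, n = 4) in OP50 hermaphrodites, 7032560 ± 1262000 in PA14 hermaphrodites, 4836990 ± 1831000 in OP50 males and 5324340 ± 1311000 in PA14 males.

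Transcripts of the major sperm proteins, the cytoskeletal proteins of crawling sperm, summed to 6060 ± 983 CPM in OP50 males against 562 ± 217 CPM in OP50 hermaphrodites (SD, n = 4 each). The lowest male library of either bacterium stood at 5049 CPM and the highest hermaphrodite library at 1181 CPM, so that no label of sex was swapped. This does not show that the male libraries were free of hermaphrodite RNA. Their oocyte and eggshell transcripts stood at 52.74% of the hermaphrodite level on OP50 and 50.21% on PA14. The yolk protein genes summed to 22900 ± 5950 CPM in OP50 hermaphrodites and 13300 ± 4080 CPM in OP50 males. The first principal component held 38.7% of the variance and parted the sexes. The second, with 29.8%, was positive for replicates 1 and 2 and negative for replicates 3 and 4 in all 4 groups. Counts for these pairs of replicates alone are therefore given beside the pooled ones.

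**Figure D1:**
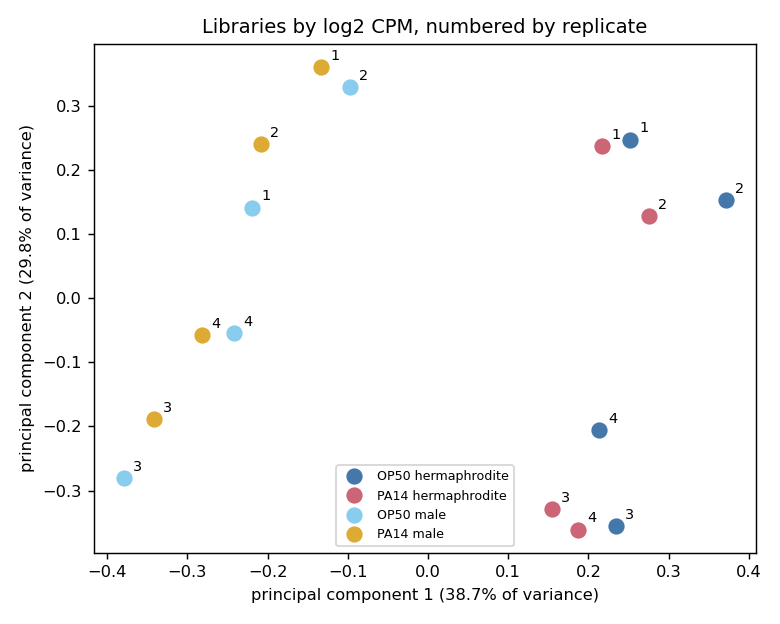
Principal components 1 (38.7% of the variance) and 2 (29.8%) of log2 CPM, 1 point per library, numbered by replicate, with a colour for each group. Hermaphrodites lie at positive and males at negative values of component 1, and replicates 1 and 2 lie at positive and replicates 3 and 4 at negative values of component 2.

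The first comparison asked which transcripts differed in hermaphrodites between PA14 and OP50. The C-type lectin gene clec-4 (chromosome II, 12578331 to 12581113), a known member of the response to Pseudomonas infection, rose from 5.67 ± 0.422 to 189 ± 65.7 CPM (SD, n = 4). Its log2 fold change was 5.06 ± 0.41 (SE) with an adjusted p of 3e-06. A second lectin gene, clec-3 (chromosome II, 3017468 to 3019907), rose by 4.11 ± 0.33 on the log2 scale, with an adjusted p of 3e-06, and overlaps C41H7.2 on the opposite strand. The infection response gene irg-3 (chromosome V, 2592591 to 2595062) rose from 10.4 ± 3.84 to 151 ± 70.3 CPM, a log2 change of 3.86 ± 0.39 (adjusted p = 3.9e-05). The folate transporter family gene folt-2 (chromosome V, 2872465 to 2875600) fell from 655 ± 96 to 23.7 ± 5.09 CPM, a log2 change of -4.79 ± 0.33 (adjusted p = 1e-06). For each gene of this paragraph all 4 libraries of one group lay beyond all 4 of the other.

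In all, 52 genes were higher and 33 lower on PA14 among the 8648 tested, and 458 genes had an unadjusted p under 0.05 where chance alone would give 432. The fit that paired the libraries by replicate number called 125 higher and 87 lower genes and kept all 85. DESeq2 gave 111 and 74, and the paired fit to only the 8 libraries 291 and 219, with 82 of the 85 kept. Replicates 1 and 2 alone gave 7 higher and 2 lower, replicates 3 and 4 alone 43 higher and 16 lower. The counts fell to 30 higher without OP50 hermaphrodites replicate 2 and to 15 lower without PA14 hermaphrodites replicate 4.

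Genes of defence and detoxification were among those that rose. Of the 18 infection response genes tested, 6 rose over all genes tested and 13 adjusted over the list alone, with a median log2 change of 2.46. The list test gave an adjusted p of 1.2e-39, and 2.5e-05 with an estimated correlation. Among its members, F08G5.6 (irg-4) rose by 2.56 ± 0.45 on the log2 scale with an adjusted p of 0.0074, while zip-2, a transcription factor of this response, gave 0.72 ± 0.27 with an adjusted p of 0.557. The call of F08G5.6 was lost at 0.065 without OP50 hermaphrodites replicate 2. Of 83 C-type lectin genes 9 rose and 1 fell (15 and 1 adjusted over the list alone), a call with an adjusted p of 9.9e-06 that was lost at adjusted p = 0.2 with an estimated correlation. Among them clec-66 rose from 30.1 ± 7.25 to 227 ± 53.3 CPM, by 2.91 ± 0.25 on the log2 scale (adjusted p = 5.6e-06). The glutathione S-transferase gene gst-38 (chromosome V, 15915162 to 15916070) rose from 50.5 ± 31.1 to 1180 ± 845 CPM, by 4.55 ± 0.61 on the log2 scale (adjusted p = 0.0007). The transferase list gave an adjusted p of 0.012 with 1 of 16 genes higher and 2 adjusted over the list alone, against adjusted p = 0.22 with an estimated correlation. It missed the threshold, at 0.075, without PA14 hermaphrodites replicate 4.

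Several families showed a few strongly changed members. The transporter gene pgp-5 stood at 2 counts in the OP50 libraries, and its ratio was 116 (95% counting interval 31.9 to 966). For dod-17 the ratio was 70.2 (12.3 to 2810) from 1 count, and for clec-174 it was 34.8 (11.6 to 171) from 3 counts. The P-glycoprotein list gave an adjusted p of 0.029, but adjusted p = 0.17 with an estimated correlation and 0.063 without PA14 males replicate 3. Of 7 dod genes, named for lying downstream of DAF-16, 2 rose (3 adjusted over the list alone) and the list gave an adjusted p of 4.3e-07, and 0.0098 with an estimated correlation. Of 27 F-box genes 2 rose (3 adjusted over the list alone), among them fbxa-128 by 4.77 ± 0.67 on the log2 scale, with an adjusted p of 0.001, and the list held at an adjusted p of 0.04 with an estimated correlation. Other genes that rose included H02F09.3, which overlaps H02F09.2, and dct-17, C49G7.12 and ugt-31, with log2 changes of 4.65, 4.4, 4.25 and 4.16. The calls of dct-17 and clec-174 were lost, at 0.052 without OP50 hermaphrodites replicate 2 and at 0.079 without OP50 hermaphrodites replicate 4.

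Lysozyme and protease genes moved in both directions. The lysozyme genes lys-1 and lys-2 rose by 1.71 ± 0.33 and 2.71 ± 0.62 on the log2 scale, while the invertebrate-type lysozyme gene ilys-5 fell from 509 ± 175 to 75.8 ± 24 CPM. Both lys calls were lost without OP50 hermaphrodites replicate 4, at 0.073 and 0.2. The cathepsin B family gene cpr-3 rose by 2.29 ± 0.39, with an adjusted p of 0.0056, while cpr-5 and asp-13, an aspartyl protease gene, had log2 changes of -1.53 and -3.07 and lost their calls at 0.061 without PA14 hermaphrodites replicate 4 and at 0.13 without PA14 hermaphrodites replicate 1. The protease list itself was not called, with an adjusted p of 0.77, nor was the lysozyme list, with 0.81. Markers of the intestine, where many of these genes are expressed, were themselves higher on PA14 (median log2 change 0.67, adjusted p = 0.0017, and adjusted p = 0.084 with an estimated correlation), and the intermediate filament gene ifb-2 was the only 1 of 12 to pass, with an adjusted p of 0.022 that became 0.12 without OP50 hermaphrodites replicate 4.

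Genes of propionate and methionine metabolism were lower on PA14. Of the 5 genes of the propionate shunt, a route that breaks propionate down without vitamin B12, 1 fell and 4 fell adjusted over the list alone, with a median log2 change of -2.26. The list test gave 7e-14, and 8.6e-05 with an estimated correlation. Its member hphd-1 (Y38F1A.6, chromosome II, 12994354 to 12996571) fell from 46.1 ± 21.9 to 2.75 ± 0.923 CPM, by a log2 change of -4.05 ± 0.57 (adjusted p = 0.0011). The first enzyme of the route, acdh-1, gave -4.43 ± 1.05 with an adjusted p of 0.0546. Of 11 methionine cycle genes 2 fell, also adjusted over the list alone, and the list gave 3.1e-07, and 0.0012 with an estimated correlation. These were the S-adenosylmethionine synthetase gene sams-1 (chromosome X, 11965962 to 11969893), from 652 ± 253 to 116 ± 51.5 CPM with an adjusted p of 0.0093, and pmt-2, a methyltransferase gene of phosphatidylcholine synthesis, with -1.4 ± 0.28 and 0.019. The call of pmt-2 was lost at 0.14 without PA14 hermaphrodites replicate 1, and that of sams-1 at 0.23 in replicates 3 and 4 alone (range over all settings 2.1e-07 to 0.23).

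Some genes of fat metabolism fell. Of 32 beta oxidation genes 16 had a positive and 16 a negative change and 3 fell, among them ech-7 (-2.05 ± 0.39 on the log2 scale, adjusted p = 0.013) and the thiolase gene kat-1 (-1.19 ± 0.24, adjusted p = 0.021). Adjusted over the list alone 7 fell and 1 rose. The list test was negative at 2.2e-05, and 0.02 with an estimated correlation, with a mean of -0.43 but a median of 0.04. This list also held acdh-1 and ech-6 of the propionate shunt. The call of kat-1 was lost at 0.11 without PA14 hermaphrodites replicate 1. The delta-9 desaturase gene fat-5, which overlaps twk-42 on the opposite strand, fell by 2.62 on the log2 scale with an adjusted p of 0.0027. It was the only 1 of 14 fatty acid synthesis genes that fell, and that list was not called (0.071, and 0.17 with an estimated correlation). The short-chain dehydrogenase gene dhs-25 had -2.75 ± 0.36 with 0.00063. Other genes that fell included F15E6.4, pmp-5, the nuclear receptor gene nhr-114 and Y43C5A.7, with log2 changes of -4.43, -3.97, -3.42 and -3.01. The calls of pmp-5 and nhr-114 reached 0.1 and 0.081 without PA14 hermaphrodites replicates 1 and 4 in turn.

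**Figure D2:**
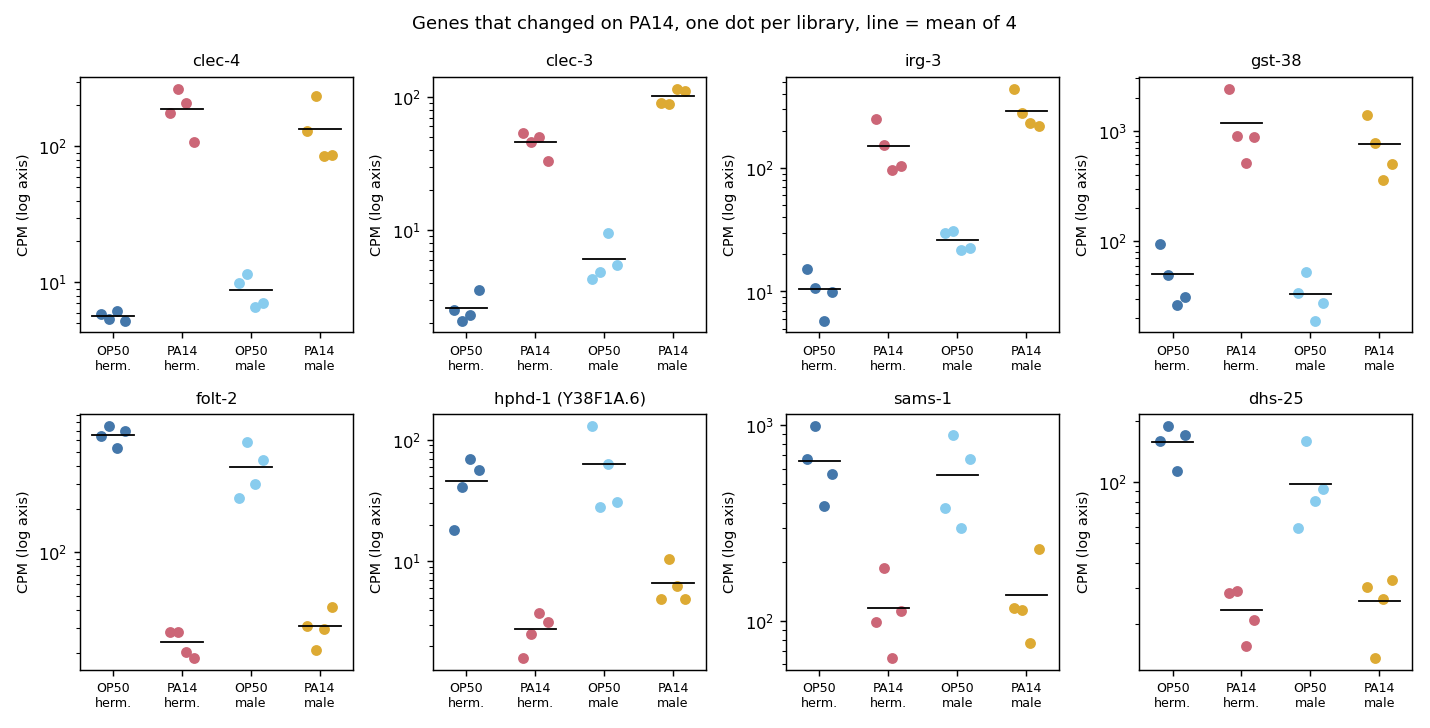
CPM on a log axis of 8 genes in the 16 libraries, with 1 point per library and a line at the mean of 4 replicates of each group. The genes clec-4, clec-3, irg-3 and gst-38 were higher, and folt-2, hphd-1 (Y38F1A.6), sams-1 and dhs-25 lower, in the PA14 means of both sexes, with sams-1 past the threshold in hermaphrodites and at an adjusted p of 0.0596 in males.

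The second comparison asked the same of males. There clec-3 rose from 6.03 ± 2.34 to 101 ± 13.8 CPM (SD, n = 4), a log2 change of 4.04 ± 0.32 with an adjusted p of 7.8e-06. The infection response gene irg-3 rose from 26.3 ± 4.79 to 291 ± 101 CPM (3.47 ± 0.38, adjusted p = 0.00012), and clec-4 rose by 3.94 ± 0.39 (adjusted p = 3.3e-05). H02F09.3 rose by 5.38 ± 0.5 with an adjusted p of 1.4e-05, and gst-38 rose from 33.2 ± 14.1 to 762 ± 463 CPM (4.53 ± 0.61, adjusted p = 0.0012). The lysozyme gene ilys-5 fell by 2.23 on the log2 scale with an adjusted p of 0.0078, and folt-2 fell from 390 ± 153 to 30.8 ± 8.61 CPM (-3.66 ± 0.32, adjusted p = 8.8e-06). All 4 libraries of one group lay beyond all 4 of the other for these genes.

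In males 17 genes were higher and 13 lower on PA14, and 428 had an unadjusted p under 0.05 where chance would give 432. Replicates 1 and 2 alone gave 6 higher and 1 lower, replicates 3 and 4 alone 10 higher and 4 lower. DESeq2 gave 71 and 54, a covariate for these pairs of replicates 56 and 45, the replicate number as a block 51 and 58 and library size alone 40 and 41. Only the 8 libraries compared gave 19 and 3, and with the block as well 11 and 4, which kept 10 of the 30 calls. The replicate numbers did not pair the male samples, as described below, which limits both fits with the block. The higher count rose to 30 without OP50 hermaphrodites replicate 1, and the lower count ranged from 4 without PA14 males replicate 1 to 20 without PA14 hermaphrodites replicate 3.

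The infection response list again had the smallest p of the 50 lists tested, with a median log2 change of 1.71 and an adjusted p of 1.5e-28, and 0.00012 with an estimated correlation. Of its 18 genes 2 rose, and 8 adjusted over the list alone. Of 83 C-type lectin genes 3 rose (10 rose and 1 fell adjusted over the list alone), with an adjusted p of 3.2e-09 for the list and adjusted p = 0.095 with an estimated correlation. Among them clec-66 rose from 32.9 ± 7.08 to 247 ± 14.4 CPM (2.91 ± 0.25, adjusted p = 8.8e-06). No dod gene passed over all genes and 2 rose adjusted over the list alone, with 3.3e-05 for the list and 0.027 with an estimated correlation. Among the other named genes that rose, fbxa-128, dct-17, oac-32, F25A2.1 and mul-1 had log2 changes of 4.07, 4.26, 3.74, 3.45 and 3.41. Leaving out OP50 males replicate 2 ended the calls of oac-32, F25A2.1 and mul-1, at 0.14, 0.12 and 0.059, and leaving out OP50 males replicate 1 that of dct-17, at 0.096. The intestine markers had a median log2 change of 0.43 and an adjusted p of 0.055.

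Propionate shunt genes were lower in males as well, with 2 of 5 past the threshold and 3 adjusted over the list alone. The list had a median log2 change of -1.93 and an adjusted p of 4.3e-10, and 0.00047 with an estimated correlation. The acyl-CoA dehydrogenase gene acdh-1 (chromosome I, 6497436 to 6499560) fell from 65.3 ± 68.7 to 0.867 ± 0.618 CPM, with an adjusted p of 0.022 that became 0.13 without PA14 males replicate 3. The call of hphd-1 (-3.25 ± 0.55, adjusted p = 0.011) became 0.075 without PA14 males replicate 1. Of 11 methionine cycle genes 1 fell (3 adjusted over the list alone), and the list gave 4.2e-06, and 0.0033 with an estimated correlation. This was pmt-2, with -1.58 ± 0.28 on the log2 scale and an adjusted p of 0.014, which became 0.19 without OP50 males replicate 4. Beta oxidation genes (1 of 32 fell, 8 adjusted over the list alone) gave 1.1e-05, and 0.021 with an estimated correlation. The 1 that fell was acdh-1, which with ech-6 belongs to the propionate shunt list as well. Fatty acid synthesis genes (1 of 14 fell, 2 adjusted over the list alone) gave 0.0032, and 0.03 with an estimated correlation. The member that fell in this last list was fat-5, by 2.12 on the log2 scale, with an adjusted p of 0.022 that became 0.11 without PA14 males replicate 1. The other named genes that fell were pmp-5, asp-13, F15E6.4, F46F2.3 and dhs-25, with log2 changes of -4.47, -4.11, -3.6, -2.64 and -1.91. Of these only F15E6.4 stayed past the threshold whichever library was left out, and the others reached 0.15 (pmp-5, without PA14 males replicate 2), 0.08 (asp-13, without PA14 males replicate 3), 0.14 and 0.083 (F46F2.3 and dhs-25, without OP50 males replicate 2).

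The third question, raised by the title of the series, was whether the sexes differed in their response. Of the genes called in either sex, 88 in all, every one moved in the same direction in both. The calls shared 16 higher genes, where independent lists would share 0.1, and 11 lower genes, where they would share 0.05. These numbers depended on the setting, with 57 and 36 by DESeq2, 50 and 34 with the covariate, 46 and 46 with the block, 15 and 3 in only the 8 libraries compared and 11 and 3 there with the block. Leaving out PA14 males replicate 1 reduced the 11 to 4, and leaving out OP50 hermaphrodites replicate 1 raised the 16 to 25. Within replicates 1 and 2 the sexes shared 6 higher genes and 1 lower, within replicates 3 and 4 they shared 10 and 4. The 52 higher genes of hermaphrodites had a median log2 change of 2.82 there and 1.94 in males. The 17 of males had 3.45 in males and 3.83 in hermaphrodites. Across the tested genes, which are not independent replicates, the fold changes of the sexes correlated with r = 0.467 and rho = 0.197, and r was 0.24 without PA14 hermaphrodites replicate 1.

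**Figure D3:**
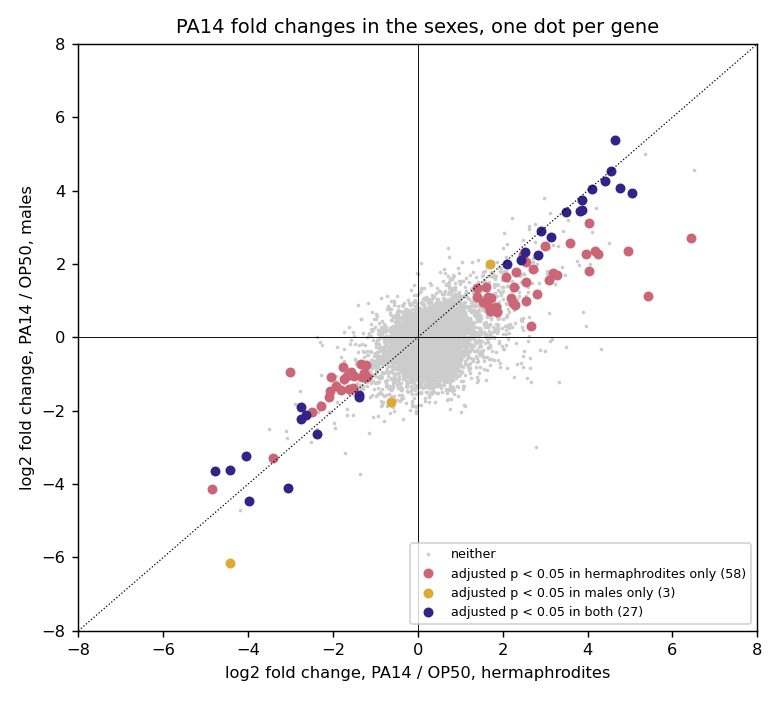
Log2 fold change on PA14 in hermaphrodites (x axis) and males (y axis) of the 8648 tested genes, with a dotted line of equal change. Genes called in neither sex are small grey points. The 88 called genes, 58 in hermaphrodites only, 3 in males only and 27 in both, are larger coloured points and lie in the same direction on both axes.

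No gene passed the test of the difference between these responses by edgeR's quasi-likelihood test, with 95 genes at an unadjusted p under 0.05 against 432 from chance. DESeq2 also gave 0, with 121 such genes, and limma-voom 0 with 94. With the replicate number as a block there were 0 and 299, with a smallest adjusted p of 0.76. The covariate for replicates 1 and 2 against 3 and 4 gave 0 and 288, with a smallest adjusted p of 0.25. Replicates 1 and 2 alone and replicates 3 and 4 alone again gave 0. For clec-4 the response of males minus that of hermaphrodites was -1.12 ± 0.49 on the log2 scale, for folt-2 it was 1.13 ± 0.41, and both had an adjusted p of 1. On simulated data the fit without a block recovered 3 of 100 genes given a 4-fold difference and 0 of 100 given a 2-fold one. Most single differences of these sizes were thus not detectable by that fit. Its dispersions hold the split of replicates 1 and 2 from 3 and 4 as noise, and fits with a block or covariate were not simulated. The 95 genes against 432 from chance also mean that this fit was conservative here, so that 0 calls do not show equal responses. Whole lists did differ at the preset correlation, and none did with an estimated one. Infection response genes had a median difference of -0.87 (males minus hermaphrodites, adjusted p = 9e-04), with adjusted p = 0.23 with an estimated correlation, and had F08G5.6 at -1.56 ± 0.6. Ribosomal protein genes had a positive median difference of 0.37 with an adjusted p of 4e-18, and adjusted p = 0.68 with an estimated correlation.

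The last pair of comparisons set males against hermaphrodites on each bacterium. Sperm genes gave the smallest p of all lists, with 29 of 30 major sperm protein genes higher in males on OP50 and again on PA14, and all 30 adjusted over the list alone. Their median log2 changes were 3.25 and 3.45. The list gave 9.2e-23 and 2.6e-27, which became adjusted p = 0.22 and adjusted p = 0.11 with an estimated correlation. Members of this family are near identical, so that single ones such as msp-50 (328 ± 84.1 against 31.2 ± 13.5 CPM on OP50) are uncertain. Of 45 spermatogenesis genes 37 were higher and 1 lower on OP50, and 34 and 2 on PA14 (40 and 2, and 38 and 2, adjusted over the list alone), with 1.1e-22 and 4.4e-24 for the list and adjusted p = 0.2 and adjusted p = 0.11 with an estimated correlation. Among them ssp-19 rose by 3.8 ± 0.37 on the log2 scale on OP50 with an adjusted p of 1.7e-05, and by 4.07 ± 0.38 on PA14 with 1.6e-05, without overlap between the sexes.

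Genes of male tissues and of the body wall were also higher in males. The DM domain gene mab-3, a regulator of male development, rose by 3.09 ± 0.52 on OP50 (adjusted p = 0.00041) and 3.23 ± 0.52 on PA14 (adjusted p = 3e-04). The polycystin gene pkd-2 of male sensory neurons rose by 4.24 ± 0.8 and 5.01 ± 0.84, with adjusted p of 0.0012 and 0.00048. A further gene of these neurons, cwp-5, had no count in hermaphrodites and was at least 9.87-fold higher in OP50 males and at least 21.2-fold higher in PA14 males, against a floor of 3 counts over the group, with 3 of 4 OP50 males above all hermaphrodites. Of the 3 tested genes of the male sensory neuron list 2 rose on each bacterium (3 adjusted over the list alone), with 0.072 for the list on OP50 and 0.015 on PA14, and adjusted p = 0.14 with an estimated correlation on PA14. The PA14 call of this list was at 0.05 without PA14 males replicate 1. C-type lectin genes were frequent, with 44 of 83 higher and 2 lower on OP50 and 39 higher and 3 lower on PA14 (52 and 3, and 44 and 4, adjusted over the list alone). The list gave 1.1e-10 and 8.1e-12, and adjusted p = 0.22 and adjusted p = 0.11 with an estimated correlation. Its members clec-133 and clec-94 rose by 4.33 ± 0.48 and 4.45 ± 0.53 on OP50. Of 140 collagen and cuticle genes 70 were higher on OP50 and 38 on PA14 (79 and 63 adjusted over the list alone), with 1.1e-11 and 6.7e-08 for the list and adjusted p = 0.57 and adjusted p = 0.69 with an estimated correlation. Muscle markers (7 and 10 of 15 higher, 9 and 11 adjusted over the list alone) included the myosin gene myo-3, with 1.08 ± 0.21 on OP50 and 0.89 ± 0.21 on PA14. That list gave 0.0099 and 0.00068, with adjusted p = 0.57 and adjusted p = 0.5 with an estimated correlation, and 0.055 on OP50 without OP50 hermaphrodites replicate 3.

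Neuronal and immune genes were also among those higher in males. Of 41 neuropeptide genes 12 were higher on OP50 and 11 on PA14 (19 and 13 adjusted over the list alone), such as nlp-9 with 1.54 ± 0.39 and 1.66 ± 0.39 on the log2 scale. The list gave 0.0036 and 0.00043, with adjusted p = 0.56 and adjusted p = 0.39 with an estimated correlation. The neuropeptide processing genes egl-3 and egl-21 rose by 1.34 ± 0.26 and 1.15 ± 0.26 on OP50, with adjusted p of 0.0015 and 0.0043, while the pan-neuronal list was not called (0.24 on OP50, 0.086 on PA14). Of the 18 infection response genes 5 were higher in males on OP50 (10 adjusted over the list alone), among them F08G5.6 by 2.58 ± 0.45 with an adjusted p of 0.0006 and irg-3 by 1.34 ± 0.36 with 0.014. The list gave 0.019, adjusted p = 0.44 with an estimated correlation, and 0.067 without OP50 males replicate 3. On PA14 it gave 0.33.

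Oocyte and yolk genes were lower in males. Of 28 oocyte and eggshell genes 14 were lower on OP50 and 8 on PA14, and 18 on each adjusted over the list alone. The list gave 1.6e-09 and 4.8e-09, with adjusted p = 0.34 and adjusted p = 0.29 with an estimated correlation. The oocyte maturation gene oma-2 had -1.34 ± 0.27 on each bacterium, with adjusted p of 0.0017 and 0.002, and the yolk receptor gene rme-2 had -1.21 ± 0.3 on PA14. Of 6 yolk protein genes 1 was lower on OP50 and 3 on PA14 (6 and 4 adjusted over the list alone), with 0.0056 and 0.00068 for the list, and adjusted p = 0.57 and adjusted p = 0.5 with an estimated correlation. Of these vit-4 had -1.13 ± 0.35 on OP50 and -1.63 ± 0.36 on PA14, though it belongs to a group of near identical genes and its OP50 call was lost at 0.083 without OP50 males replicate 3. In males the oocyte and eggshell transcripts still stood at 52.74% of the hermaphrodite level on OP50 and 50.21% on PA14, and the yolk transcripts at 58.05% and 50.68%. In hermaphrodites the major sperm protein transcripts stood at 9.27% and 9.92% of the male level. Germline genes (1 and 3 of 36 lower, 0 and 0 adjusted over the list alone) gave 0.019 and 0.00068, with adjusted p = 0.54 and adjusted p = 0.25 with an estimated correlation, and 0.055 on OP50 without OP50 hermaphrodites replicate 3.

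**Figure D4:**
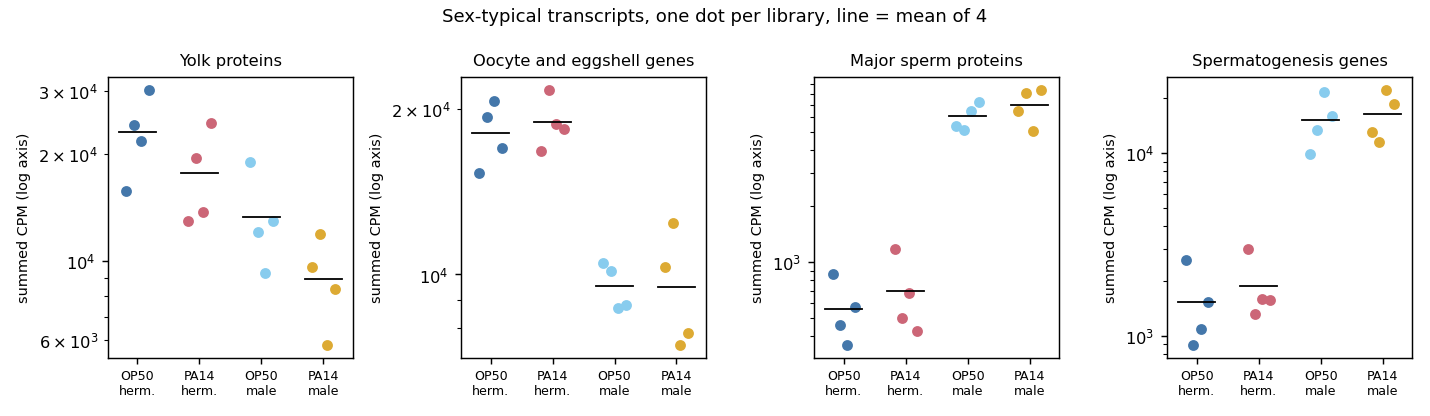
Summed CPM, on a log axis, of the yolk protein, oocyte and eggshell, major sperm protein and spermatogenesis genes in the 16 libraries, with 1 point per library and a line at the mean of 4. Oocyte and eggshell transcripts had means of 18100 CPM in OP50 hermaphrodites and 9530 CPM in OP50 males, and major sperm protein transcripts of 562 and 6060 CPM.

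Of the 10 genes that the rule of the largest folds named as higher in males on OP50, 8 had 1 or 2 counts in hermaphrodites, among them F18E9.7 with a ratio of 250 (44.3 to 9910), Y49F6B.13 with 171 (30.2 to 6810) and ZK858.8 with 165 (29 to 6560). The others were msd-2, which overlaps F44D12.16, and R09E10.8, whose call was lost at 0.11 without OP50 males replicate 1. On PA14 those named first were msd-2 with 6 ± 1.53, scl-8 with 5.81 ± 0.69 and C48B4.12 with 5.61 ± 0.79 on the log2 scale. Of the genes lower in males, the caveolin gene cav-1 had -1.95 ± 0.3 on OP50 (adjusted p = 0.00018), and the sex determination gene fem-3 and the germline gene gls-1 had -2.14 ± 0.39 and -2.38 ± 0.47 on PA14 (adjusted p = 0.00091 and 0.002). Of the genes named by that rule, those lowest in males were linc-6 on OP50 (-2.16 ± 0.59), lost at 0.066 without OP50 males replicate 3, and C05D9.12 on PA14 (-3.01 ± 0.9), lost at 0.091 without PA14 hermaphrodites replicate 4.

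On OP50, 1367 genes were higher and 312 lower in males, and on PA14 1178 and 281, with 2662 and 2417 genes at an unadjusted p under 0.05 against 432 from chance. On PA14, the fit of all 16 samples with the replicate number as a block gave 1571 higher and 773 lower. Fitted to only the 8 PA14 libraries, the block called 1244 genes and kept 1035 of the 1459. Replicates 1 and 2 alone gave 533 higher and 30 lower on OP50 and 361 and 18 on PA14, replicates 3 and 4 alone 1562 and 194 on OP50 and 1509 and 435 on PA14. The count of lower genes depended on the model, the scaling and single libraries. On OP50 it was 945 with the replicate number as a block, 887 by DESeq2, 810 with the covariate, 171 with a fold minimum of 1 on the log2 scale, 597 with the size factors of DESeq2, 188 without OP50 males replicate 3 and 523 without OP50 males replicate 2. On PA14 it was 731 with the covariate, 618 by DESeq2, 116 in only the 8 libraries compared, 169 with the fold minimum, 671 with library size alone, 164 without PA14 hermaphrodites replicate 2 and 513 without OP50 hermaphrodites replicate 1. The share of called genes that were higher in males, 81.4% on OP50 and 80.7% on PA14, was 68.7% on OP50 and 75.2% on PA14 with the size factors of DESeq2, and 76.9% and 65.6% with library size alone. Hermaphrodite RNA in the male libraries, left open below, would limit how far a gene could fall in males. From 20 CPM upward in hermaphrodites, 0 of 2786 genes on OP50 and 0 of 2882 on PA14 stood under 10% of it in males. From 20 CPM upward in males, 292 of 3115 and 286 of 3116 stood under 10% of it in hermaphrodites. Whether such RNA shaped these counts was not tested.

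Because the title of the series names receptors related to those of neuropeptide Y, the npr genes were listed separately. The 4 that could be tested were npr-21, npr-28, npr-36 (F10D7.1, which overlaps F10D7.11) and npr-37 (M04G7.3). None passed in any comparison. On PA14 their log2 changes were -0.38, 0.07, 0.38 and -0.39 in hermaphrodites and 0.22, -0.27, 0.13 and 0.37 in males, and every adjusted p was 1. For the list the adjusted p was 0.73 in hermaphrodites, 0.54 in males, 0.34 for the difference of the responses, and 0.77 and 0.99 between the sexes. The receptor gene npr-5 was too low to be tested, with 28 and 23 counts in OP50 and PA14 hermaphrodites and 28 and 5 in OP50 and PA14 males. Without the filter on low counts its log2 change on PA14 in males was -2.66 ± 0.91 with an adjusted p of 0.56. The TGF-beta gene daf-7 had 8.43 ± 2.7 CPM in OP50 males and 2.66 ± 0.983 CPM in OP50 hermaphrodites (log2 change 1.65 ± 0.45, adjusted p = 0.014), and 9.53 ± 2.61 against 3.18 ± 1.47 CPM on PA14 (1.59 ± 0.44, adjusted p = 0.019). These calls were lost at 0.053 without OP50 hermaphrodites replicate 2 and at 0.067 without PA14 hermaphrodites replicate 4. Between PA14 and OP50 it had 0.24 ± 0.44 in hermaphrodites and 0.18 ± 0.43 in males, both with an adjusted p of 1.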

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

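All tests of an explanation given here were chosen after the results they address had been seen, apart from the counts over other splits of the samples, which were planned except for the splits and draws that kept pairs or balanced replicates 1 and 2 against 3 and 4. Male libraries held oocyte and eggshell transcripts at 52.74% of the hermaphrodite level on OP50 and 50.21% on PA14, and 27 oocyte and yolk genes with at least 100 CPM had medians of 49.9% and 47.4%. Exchange of reads between pooled libraries would carry sperm transcripts into hermaphrodite libraries at a like share, and the highest level of these there was 11.36% of the male level, which argues against it as the source of the whole level. Hermaphrodite animals or their RNA in the male samples were tested as the source of the whole level, and 0 of 1200 abundant genes on OP50 and 0 of 1172 on PA14 lay below that share by an adjusted one-sided test on the edgeR values. By the unadjusted test 4 and 1 genes lay below it, where chance would give at most 60 and 59. At these errors a male level at 0.5 of the share would pass for only 3 genes on each bacterium. At 0.5 of that level again 774 genes on OP50 and 752 on PA14 would pass, and 0 did. Values under the share were those of cav-1 at 25.9% on OP50 (SE 0.3 on the log2 scale), fem-3 at 22.7% on PA14 (SE 0.39) and EEED8.3 at 18% on PA14 (SE 0.89), among others. For levels nearer to the share the test therefore decides little. Of the 27 oocyte and yolk genes 0 lay more than 2 standard errors from their median on either bacterium. A smaller admixture stays open, but its upper limit is not set by these abundant genes. The less abundant C05D9.12, named above, stood at a lower share on PA14 than any of them. The lowest abundant oocyte or yolk gene at 29.9% leaves open that males transcribed the oocyte and yolk genes. An admixture and the males' own transcription therefore cannot be told apart with these genes' errors.

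Replicates 1 and 2 parted from replicates 3 and 4 in all 4 groups, with 3918 of 8648 genes called between them, 1752 higher and 2166 lower in replicates 3 and 4. A difference in depth is argued against, because 2998 of 7208 tested genes were still called after all libraries were thinned to 3011817 counts. At that total replicates 3 and 4 held more genes with a count than replicates 1 and 2 in all 4 groups. The means were 10312 against 9227 in OP50 hermaphrodites, 10762 against 9813 in PA14 hermaphrodites, 11268.5 against 10585 in OP50 males and 11075.5 against 10820.5 in PA14 males. The source of this was not tested. Deviations from the group means correlated with a median of 0.51 between libraries of different groups on the same side and -0.47 across sides, and centring on group means makes the second negative by construction. Shared handling of these pairs of replicates may therefore be the source but cannot be told apart from a difference in the age or state of the animals, since the labels give no dates. No biological explanation was tested, as the design gives no group that follows this split.

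Propionate shunt and methionine cycle genes were lower on PA14 in both sexes, and the largest of the 4 adjusted p of these lists with an estimated correlation was 0.0033. A candidate explanation is that PA14 supplied more vitamin B12 than OP50, since the vitamin is known to lower the transcripts of the shunt. B12 was not measured, and the test restates the pattern, so that this stays open beside any other difference between the bacteria as food. A lower share of transcripts of the intestine, the site of much of this metabolism, is argued against only as far as the intestine markers gauge it. These had positive medians of 0.67 in hermaphrodites and 0.43 in males. Their list was not called in males, nor in hermaphrodites with an estimated correlation. Whether these markers themselves respond to the bacterium was not tested. The bacterium itself is the biological difference named by the design, and its route was not tested.

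Over all splits of the same 8 libraries, 1 of 35 gave as many genes between the sexes on OP50 as the real 1679, with 0 as the highest other, and 1 of 35 on PA14 as the real 1459, with 1 as the highest other. For PA14 in hermaphrodites 2 of 35 splits gave at least the real 85 genes, and in males 2 of 35 gave at least 30. The other split in each was that of replicates 1 and 2 against 3 and 4, with 2871 and 459 genes, which points to a structure of the samples. The highest of the remaining splits gave 0 and 2, and within replicates 1 and 2 and within 3 and 4 genes were called in hermaphrodites (7 higher and 2 lower, 43 and 16) and in males (6 and 1, 10 and 4). As these pairs of replicates part in all groups, only the 18 splits that balance them compare with the real ones. In hermaphrodites the 8 splits that part all equal numbers were used. There each OP50 sample correlated best with its own number, though PA14 replicate 4 did not. These 8 were also used between the sexes on PA14, where equal numbers correlated but not always best. The highest other of these gave 0 genes in all 4 comparisons, too few splits for a share under 0.05.

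Shared calls of both sexes were 27, with 1 of 100 draws of labels as high and 0 as the highest other. The same held in draws that kept the pairs of hermaphrodites and balanced replicates 1 and 2 against 3 and 4 in males. Outside the split of replicates 1 and 2 against 3 and 4, relabelling called 0 genes in hermaphrodites and at most 2 in males. A draw could therefore hardly share genes. The draws address the responses of both sexes at once and cannot decide whether the sexes share genes beyond chance. Hermaphrodite RNA in the male libraries, left open above, would carry the response of hermaphrodites into them, so that it may be a source of part of the shared calls and directions. Such RNA could also make a difference of the responses look smaller. For irg-3 such RNA would not give the whole rise, since PA14 males had 291 ± 101 CPM (SD, n = 4) and PA14 hermaphrodites 151 ± 70.3, and for the other genes this was not tested. For the difference of the responses the real count was 0, so that 100 of 100 draws were as high by construction (highest other 1430) and the draws decide nothing. Chance could not be excluded for the numbers of lists called, where 5 of 35 splits reached 16 in hermaphrodites (highest other 20), 15 of 35 reached 12 on OP50 (17), 15 of 35 reached 10 on PA14 (18) and 68 of 100 draws reached 6 for the difference (21). In males 3 of 35 splits reached 16 lists (highest other 18), and the highest other of the 18 balanced splits gave 15, too few for a share under 0.05.

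A difference between the sexes in the response to PA14 was called for 6 lists at the preset correlation and for none with an estimated one. The values below are males minus hermaphrodites, and no member gene passed over all genes tested. Infection response genes gave 9e-04 (median -0.87, adjusted p = 0.23 with an estimated correlation). Antimicrobial peptides gave 0.0013 (0.66, adjusted p = 0.78), which became 0.9 without OP50 hermaphrodites replicate 1. P-glycoproteins gave 0.0059 (-0.81, adjusted p = 0.23), or 0.1 without OP50 males replicate 4. Ribosomal proteins gave 4e-18 (0.37, adjusted p = 0.68). Nuclear genes of oxidative phosphorylation gave 0.0055 (0.15, adjusted p = 0.68). Collagen and cuticle genes gave 0.0015 (-0.19, adjusted p = 0.84), or 0.95 without OP50 males replicate 2. In the order of these lists the members with the smallest p were F08G5.6 at -1.56, nlp-27 at 1.04, pgp-5 at -3.72 (a fitted value that rests on 2 counts in OP50 hermaphrodites), rps-16 at 0.65, nuo-2 at -0.97 and col-49 at -1.86 on the log2 scale, and every adjusted p was 1.

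A single library lay far from the other 3 of its group in 52 of 649 groups examined, where chance gives about 1 in 20. In each case the value of that library is followed by the lowest and highest of the others. The 10 most abundant genes took 8.77% of the counts in OP50 hermaphrodites replicate 4 (7.45 to 7.58) and 8.63% in PA14 males replicate 3 (7.52 to 7.7). Summed collagen transcripts were 77000 CPM in PA14 hermaphrodites replicate 4 (60400 to 62400). With plain totals, lov-1 was 0.34 CPM in OP50 hermaphrodites replicate 4 (0 to 0) and mab-3 was 19.6 in PA14 males replicate 3 (11.6 to 12.4).

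OP50 hermaphrodites replicate 1 stood apart for several genes, in CPM. These were C49G7.12 at 13 (1.85 to 3.01), cpr-3 at 33.4 (9.79 to 13.3), his-16 at 5.6 (1.46 to 1.85), daf-7 at 4.13 (2.08 to 2.36), nlp-27 at 2240 (360 to 677), mxl-1 at 311 (148 to 153), F59A7.12 at 27.6 (6.91 to 9.38), fbxb-36 at 1.77 (0.834 to 0.927) and acs-2 at 91.3 (26 to 28). In the same library ZK858.8, C38C3.7, F36H1.3 and ZK892.5 were each at 0.147 (0 to 0), which is 1 count. Of the other OP50 hermaphrodites, replicate 2 had clec-133 at 2.08 (4.57 to 4.75). Replicate 3 had dod-17, F18E9.7 and Y49F6B.13 at 0.116 (0 to 0) and Y48E1B.8 at 14.2 (33.7 to 36). Replicate 4 had F26F4.2 at 0.168 (0 to 0) and sri-40 at 19.2 (14.9 to 15.6).

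In OP50 males, replicate 1 had msd-2 at 87.8 CPM (1.77 to 6.73), F36H1.3 at 14.2 (0.961 to 3.15), R09E10.8 at 61.8 (0.591 to 7.69), gst-10 at 54.7 (0.394 to 2.36), his-70 at 24.4 (3.94 to 6.1), T21C12.3 at 7.11 (13 to 13.8), msp-142 at 290 (513 to 536) and ssq-2 at 1070 (1650 to 1760). Replicate 2 had mab-3 at 20.2 (10.2 to 11.8) and nlp-27 at 1370 (568 to 632). Replicate 3 had K08D8.5 at 8.78 (3.15 to 3.84) and tnt-4 at 21.2 (28.4 to 29.2), and replicate 4 had acs-2 at 133 (198 to 210). In PA14 males, replicate 2 had oac-32 at 43.2 (4.32 to 8.43) and C49C3.11 at 25.1 (2.36 to 5.49), replicate 3 had sri-40 at 2.75 (7.45 to 8.36), and replicate 4 had msp-50 at 528 (312 to 317). In PA14 hermaphrodites, replicate 1 had ilys-5 at 111 (60.9 to 69.4), spe-38 at 80.9 (22.5 to 32.3), msp-50 at 61 (22.7 to 24.4), Y57G7A.2 at 26.6 (7.34 to 10.5) and flp-33 at 31.8 (the others at most 17). Replicate 2 had clec-174 at 6.29 (3.36 to 3.86), lys-1 at 53.7 (79 to 80.9), fbxc-50 at 159 (117 to 124), deps-1 at 509 (260 to 288) and M01E11.3 at 38.6 (13.4 to 16.6).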

How the results depend on the processing

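The covariate for replicates 1 and 2 against 3 and 4, the fits to either pair of replicates, the fit without a pair of males and the block in only the 8 samples were chosen after seeing the data. Over all alternatives, values of named genes stayed on their side of the threshold in 8804 cases, lost their call in 845, gained one in 10 and reversed in 0. Values of lists stayed in 7435 cases, lost a call in 177, gained one in 227 and reversed in 7. Counts of calls depended on the setting more than directions did, and where no construction is named the cause was not tested. On simulated data with these dispersions and 4 replicates, the fit without a block recovered 1 to 4 of 100 2-fold changes in the 4 comparisons of groups.

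With the size factors of DESeq2, 597 genes were lower in males on OP50. With library size alone, 94 genes were higher on PA14 in hermaphrodites, 40 higher and 41 lower in males and 37 and 26 in both sexes, and 484 and 671 genes were lower in males on OP50 and PA14. That scaling moved the median log2 change of all genes from 0.1 to 0.29 on PA14 in hermaphrodites, from -0.13 to -0.35 for the difference of the responses, from 0.21 to 0.32 between the sexes on OP50 and from -0.02 to -0.12 on PA14, and the size factors of DESeq2 moved the OP50 value to 0.07. No filter gave 27 genes higher on PA14 than on OP50 in males. For PA14 against OP50 the stricter filter gave 28 higher and 22 lower in males and 26 and 18 in both sexes, with fewer genes tested. DESeq2 gave 111 and 74 genes in hermaphrodites, 71 and 54 in males, 57 and 36 in both, and 887 and 618 lower in males on OP50 and PA14. A fold minimum left 171 and 169 lower in males.

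The block for replicate numbers gave 125 and 87 genes in hermaphrodites, 51 and 58 in males, 46 and 46 in both, and 945 and 773 lower in males on OP50 and PA14. In the PA14 comparison of males and the OP50 comparison of the sexes the numbers did not pair the samples, with correlations of 0 to 0.75 and -0.02 to 0.7. OP50 males replicate 1 correlated at 0.72 with PA14 males replicate 2 and at 0.28 with its own number. OP50 males replicate 2 correlated at 0.66 with PA14 males replicate 1 and at 0 with its own number. A block by number may therefore mispair these male libraries. The block fitted to all samples kept 30 of 30 and 1674 of 1679 calls in these comparisons. The covariate gave 113 and 72 genes in hermaphrodites, 56 and 45 in males, 50 and 34 in both, and 810 and 731 lower in males on OP50 and PA14, and kept 85, 30, 1678 and 1459 calls. Replicates 1 and 2 alone, with fewer samples, gave 7 and 2 genes in hermaphrodites, 6 and 1 in males, 6 and 1 in both, 533 and 30 between the sexes on OP50 and 361 and 18 on PA14. Replicates 3 and 4 alone gave 16 lower in hermaphrodites, 10 and 4 in males, 10 and 4 in both, 194 and 435 lower in males on OP50 and PA14, and 10 lists for the difference of the responses. Without OP50 males replicate 1 and PA14 males replicate 2 there were 11 and 5 genes in males and 5 lower in both. These libraries stood apart on principal component 3 (10.9% of the variance), at 0.507 and 0.547, with the others at most 0.194. Only the 8 samples compared gave 3 genes lower on PA14 than on OP50 in males and 3 lower in both. Between the sexes they gave 206 and 116 lower in males on OP50 and PA14. With the block as well they gave 291 and 219 in hermaphrodites, 11 and 4 in males and 3 lower in both, and kept 82 of 85, 10 of 30, 1209 of 1679 and 1035 of 1459 calls.

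Lists called with an estimated correlation numbered 6 and 6 on PA14 in hermaphrodites and males and 0, 0 and 0 for the difference and between the sexes. Fry gave 7, 6, 0, 31 and 23. The 7 reversals, each an adjusted p, were antimicrobial peptides in hermaphrodites (0.031) and for the difference (0.9) without OP50 hermaphrodites replicate 1 (ranges over samples left out 0.031 to 0.72 and 1.6e-06 to 0.9), P-glycoproteins in hermaphrodites in only the 8 samples (0.98), major sperm proteins in hermaphrodites without PA14 hermaphrodites replicate 1 (0.018, with the lowest, 0.017, upward without OP50 hermaphrodites replicate 1), the mitochondrial genome for the difference in replicates 1 and 2 alone (0.00024) and without PA14 hermaphrodites replicate 4 (0.047), and beta oxidation between the sexes on OP50 under fry (0.043).

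Leaving out each sample in turn gave 30 to 68 higher and 15 to 43 lower genes in hermaphrodites on PA14, 13 to 30 and 4 to 20 in males, and 13 to 25 and 4 to 13 in both, with the highest counts of hermaphrodites without PA14 males replicate 2. Between the sexes it gave 1112 to 1553 and 188 to 523 on OP50 and 959 to 1417 and 164 to 513 on PA14. The difference of the responses stayed at 0, and the correlation of fold changes at 0.24 to 0.575. Lists numbered 15 to 23, 14 to 19, 5 to 10, 9 to 13 and 9 to 13 in the order hermaphrodites, males, difference, OP50 and PA14, with 10 for the difference without OP50 hermaphrodites replicate 2. Of the named genes called, 22 of 41 in hermaphrodites, 10 of 22 in males, 75 of 108 on OP50 and 75 of 100 on PA14 kept the call whichever sample was left out, and the adjusted p of the others reached at most 0.2, 0.19, 0.62 and 0.21. Of the lists called, 10 of 16, 12 of 16, 3 of 6, 8 of 12 and 9 of 10 did.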

Other observations

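The exact tests of summed levels in this part were chosen after the values were seen. Collagen transcripts, which encode the cuticle, were lower on PA14 in both sexes. They summed to 65500 ± 7670 CPM against 98700 ± 13100 CPM in hermaphrodites and to 96300 ± 7010 against 143000 ± 15300 CPM in males (SD, n = 4), log2 ratios of -0.59 and -0.57. In each sex all 4 PA14 libraries lay below all 4 OP50 libraries. The exact permutation p was 0.0286, the smallest that 4 against 4 allows, and 0.23 adjusted over 8 measures. Over the 140 genes of the list 0 fell over all genes tested in either sex by edgeR, and 7 in hermaphrodites and 1 in males adjusted over the list alone. The list was called down with 1.3e-05 in hermaphrodites, 0.051 without OP50 hermaphrodites replicate 1, and 2e-18 in males, with adjusted p = 0.66 and adjusted p = 0.26 with an estimated correlation. Of its members col-143 in hermaphrodites had -1.21 ± 0.28 on the log2 scale with an adjusted p of 0.05, and col-93 in males -1.32 ± 0.29 with 0.073, so that neither passed.

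Yolk protein transcripts gave negative list tests on PA14, with 5.5e-06 and a median log2 change of -0.68 in hermaphrodites and 2.6e-09 and -1.23 in males, and adjusted p = 0.17 and adjusted p = 0.088 with an estimated correlation. No single yolk gene passed over all genes, with 2 and 4 of 6 adjusted over the list alone, and vit-1 had -1.97 ± 0.48 (adjusted p = 0.069) and -2.34 ± 0.49 (adjusted p = 0.054). Their sums were 17600 ± 5390 against 22900 ± 5950 CPM in hermaphrodites (exact permutation p = 0.2286, n = 4) and 8930 ± 2550 against 13300 ± 4080 CPM in males (exact permutation p = 0.1143, n = 4).

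Other lists were called on PA14 at the preset correlation alone, mostly without a member that passed. In hermaphrodites, nuclear genes of oxidative phosphorylation were down (0.00016, adjusted p = 0.25 with an estimated correlation, median -0.3), as were ribosomal proteins (0.00061, adjusted p = 0.83 with an estimated correlation), muscle markers (0.018, adjusted p = 0.52 with an estimated correlation) and hypodermis markers (0.038, adjusted p = 0.14 with an estimated correlation). Of these ribosomal proteins lost the call at 0.1 without OP50 hermaphrodites replicate 1, muscle at 0.18 without OP50 hermaphrodites replicate 4 and hypodermis at 0.08 without PA14 hermaphrodites replicate 1. The summed ribosomal protein transcripts, on plain totals, were not lower, with 291000 ± 7340 CPM on PA14 against 284000 ± 12000 CPM on OP50 (exact permutation p = 0.3714, n = 4). In males, ribosomal proteins were up (5.1e-06, adjusted p = 0.65 with an estimated correlation), as were neuropeptides (0.0032, adjusted p = 0.37 with an estimated correlation), genes of the endoplasmic reticulum stress response (0.0046, adjusted p = 0.26 with an estimated correlation), glutathione S-transferases (0.007, adjusted p = 0.26 with an estimated correlation), histones (0.013, adjusted p = 0.65 with an estimated correlation) and major sperm proteins (0.029, adjusted p = 0.7 with an estimated correlation). Glucuronosyltransferases were down in males (0.037, adjusted p = 0.62 with an estimated correlation). The calls of transferases, histones, sperm proteins and glucuronosyltransferases were lost at 0.09, 0.51, 0.32 and 0.56 without OP50 males replicate 4, OP50 males replicate 1, PA14 males replicate 4 and OP50 males replicate 3 in turn. The p38 pathway, whose kinase PMK-1 acts in immunity, was not called in hermaphrodites (0.98) or males (0.97).

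On OP50 males had lower ribosomal protein transcripts by the list test (median log2 change -0.39, 3.8e-06, adjusted p = 0.73 with an estimated correlation), while the single gene rpl-42 was higher by 3.56 ± 0.51 with an adjusted p of 0.00011. The sum was 237000 ± 17600 CPM against 284000 ± 12000 CPM in hermaphrodites (exact permutation p = 0.0286, n = 4, the smallest possible, and 0.038 adjusted over 8 measures). Histone genes had 6 lower and 1 higher of 35, with 0.019 for the list, adjusted p = 0.73 with an estimated correlation, and 0.17 without OP50 males replicate 1. Among lists not called between the sexes, the insulin-like genes ins-31 and ins-37 were higher in males by 5.04 ± 0.96 and 3.15 ± 0.56 on the log2 scale on OP50, with adjusted p of 0.0013 and 0.00071, and the cystathionine beta-synthase gene cbs-2 by 3.71 ± 0.45 with 3e-05.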
